A study of Sus scrofa with 6 samples.

How the data were processed

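The libraries were made from primary cells of pig external ear (auricular) cartilage, freed from the tissue by enzymes. All cells came from 1 pig of 4 months of age, a Duroc × (Landrace × Large White) cross with wild-type PPARD. Cells were kept for 24 h with GW0742, a synthetic agonist of the nuclear receptor PPARD, or with DMSO, the solvent, and 3 libraries were made per group. Per the labels' protocols, mRNA was captured on oligo(dT) beads, fragmented and copied with random hexamers, and the libraries were read on an Ion Proton instrument. No step that marks the strand is named, so reads of overlapping genes on opposite strands are treated here as not separable.

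The deposited library tables give, per the file headers, an estimated count of reads and an RPKM value for each gene model (reads scaled by model length and library depth). The estimated counts were made by the authors, are mostly fractional, and leave out models with no reads. The deposited series table repeats the RPKM values of the authors for 19670 models, with 0 where a library table lists none, and 0 values differed between both sources by over 0.01%. Per the submitters' processing notes the build was Sscrofa 10.2. The aligner, the counting program and the annotation release are not given in the sources used here. Estimated counts can split reads between near-identical models, so values of models that share a protein are uncertain.

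Model identifiers were matched to symbols with a gene name table, which named 11147. A further 567 were named where the protein match and the pathway identifier in the deposited annotation both led to 1 symbol, unused by any other model, through the RefSeq gene table of assembly Sscrofa11.1. Among 2449 models that could be compared, 97.6% had the same name from both routes. The remaining 7956 models have no symbol and are given by identifier, with the protein name of the deposited annotation where used. No coordinates are printed, because the reference tables belong to another build.

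Estimated counts were rounded to whole numbers. They summed to between 13133980 and 16913745 reads per library, and the 10 most abundant models took between 13.0% and 14.2%. A count of 3 reads, taken as the floor, corresponds to between 0.177 and 0.228 CPM, and covers counting error only. Chi-square values per degree of freedom between libraries of a group ranged from 4.3 to 16.0, so no pair agreed within sampling noise. The highest was between GW0742 replicates 2 and 3. Between libraries of different groups the values ranged from 10.2 to 18.0, so the ranges overlapped.

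Genes were filtered with filterByExpr by group (minimum count 10), scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, GW0742 against DMSO, without a block. Adjusted p-values are two-sided and Benjamini-Hochberg corrected over all tested genes, with a threshold of 0.05. CPM values use TMM-scaled library sizes, and the SE of a log2 fold change is its size divided by the root of its F value. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, over lists with at least 5 tested members, and again with an estimated correlation and with fry. Counts of list members past 0.05 when adjusted over the list alone are given beside those over all genes.

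The test, the 27 gene lists and the rule for named genes were set before the data were examined. The rule names PPARD, ANGPTL4, PDK4, CPT1A, PLIN2, SOX9, COL2A1, ACAN and ELN whatever their values. It also names the 8 genes with symbols that moved most in each direction among those past the threshold, at a mean of at least 1 CPM and with groups that do not overlap, and up to 3 members past the threshold in each list. PLIN2 has no symbol match, and is given by its models. A gene that the rule names is not reported here. All other named genes and models were chosen after their values were seen.

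Alternatives were median-of-ratios size factors, DESeq2 1.42.0, no filter beyond 1 read in total, leaving out each library, the replicate number as a block, limma on log2(RPKM + 1) and log2(RPKM + 0.1) of the deposited RPKM values, an adjusted p under 0.01, and a fold of at least 2. Summing models with 1 protein name, a robust prior in edgeR and lists without called genes were added after seeing the data.

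The tests were checked on simulated counts of GW0742 against DMSO with 14032 genes. Of these, 200 had known changes of 1.5-fold, 2-fold or 4-fold, and a list of 20 others had a smaller common rise. At 1.5-fold, edgeR recovered 44.8% of 67 genes, at 2-fold 80.6% of 67 and at 4-fold 90.9% of 66. Of its 163 calls, 7.4% were genes outside both sets.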

Results

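RNA was measured in primary cells of pig external ear cartilage after 24 h with GW0742, an agonist of the lipid-sensing nuclear receptor PPARD, or with DMSO, with 3 libraries per group. The series asks how PPARD bears on the growth of cartilage in the external ear. Each library held between 13133980 and 16913745 estimated reads, and 14146 gene models (71.9% of those listed) were deep enough to test. All cells came from 1 pig and the labels do not say that the cultures were separate, so p-values measure only the spread between these libraries, which may be technical.

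GW0742 raised a small set of genes of fatty acid use many-fold and aggrecan (ACAN), the main proteoglycan of cartilage, fell by 29.4%. PDK4, which shuts off pyruvate dehydrogenase, went from 0.28 ± 0.08 to 4.72 ± 0.77 CPM (SD, n = 3), a fold of 16.5 from a level of 4, 5 and 4 reads in the DMSO libraries. ANGPTL4, a secreted inhibitor of lipoprotein lipase, went from 21.3 ± 5.2 to 187 ± 12 CPM, and CPT1A, which commits long-chain fatty acids to mitochondria, from 35.3 ± 7.7 to 136 ± 8.4 CPM. ACAN fell from 816 ± 34 to 577 ± 16 CPM. In all, 26 models were higher and 11 lower with GW0742 at an adjusted p under 0.05 in edgeR, 19 and 4 of them by at least 2-fold, and 17 of the 37 have a symbol. The 4 have no symbol, with means of 1.26 to 3.13 CPM with DMSO and 0 to 0.18 CPM with GW0742. In ENSSSCG00000021842, ENSSSCG00000025809 and ENSSSCG00000030306 a change of the gene and reads passed between models of 1 protein cannot be told apart.

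**Figure D1:**
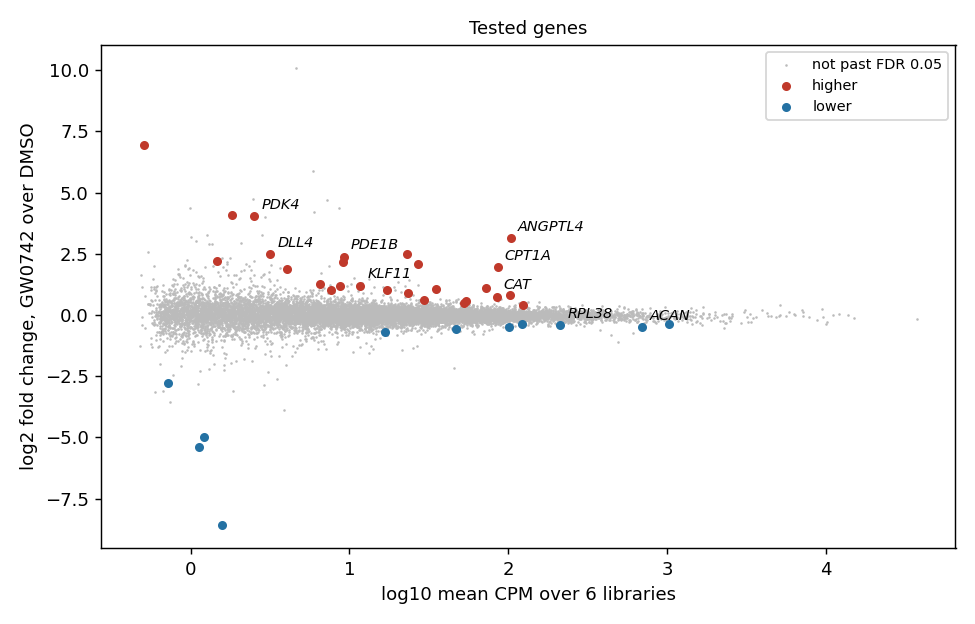
Log2 fold change (GW0742 over DMSO) against log10 mean CPM for each of the 14146 tested models. Red points mark the 26 models higher and blue points the 11 lower at an adjusted p under 0.05, with ANGPTL4 and CPT1A combining a high level with a large rise.

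The groups did not overlap in any of the 37 models, nor in 3317 of all tested models (23.4%, against 10% by chance for 3 against 3). At an unadjusted p under 0.05, 1122 models were higher and 1260 lower, against 707 in total by chance. The first principal component held 36.3% of the variance and parted the groups, while the second (23.2%) set DMSO replicate 2 apart from the other DMSO libraries. DESeq2 called 207 higher and 234 lower. Leaving out DMSO replicate 1 gave 6 higher and 0 lower, DMSO replicate 2 gave 19 and 9, DMSO replicate 3 gave 7 and 0, GW0742 replicate 1 gave 10 and 0, GW0742 replicate 2 gave 15 and 7, and GW0742 replicate 3 gave 54 and 47. Except without DMSO replicate 1, these counts include models outside the 37. At an unadjusted p under 0.05, 842 models were lower without DMSO replicate 1, 945 without DMSO replicate 3 and 1032 without GW0742 replicate 1.

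Of the 12 tested members of the PPAR target list 4 rose in edgeR and 8 did not pass there, or 5 rose when adjusted over the list alone. Camera called the list higher (adjusted p = 3.79e-22). That call rests on the genes called singly: with them left out the adjusted p was 0.496. It was also the list whose call held with an estimated correlation (adjusted p = 0.0195) and with fry (adjusted p = 0.00155). ANGPTL4 (ENSSSCG00000013599) rose by a log2 fold change of 3.14 ± 0.15 (SE, adjusted p = 0.000193) and PDK4 (ENSSSCG00000015334) by 4.05 ± 0.30 (adjusted p = 0.00151), though by 1.06 in limma on log2(RPKM + 1), where low levels are compressed. CPT1A (ENSSSCG00000012880) rose by 1.95 ± 0.14 (adjusted p = 0.00151). Catalase (CAT), which breaks down hydrogen peroxide, rose from 62.9 ± 3.1 to 106 ± 3.5 CPM (log2 0.75 ± 0.07, adjusted p = 0.00384). These calls held without any single library. SLC25A20, the carrier of acylcarnitines into mitochondria, stood at 29.2 ± 3.5 and 45.5 ± 2.5 CPM (log2 0.64, adjusted p = 0.0509), and DESeq2 called it.

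PLIN2, the coat protein of lipid droplets, is split over a pair of models without a symbol. ENSSSCG00000005171 rose from 45.5 ± 6.5 to 98.5 ± 20.4 CPM (log2 1.11 ± 0.16, adjusted p = 0.0395), a call that was lost without any one of the 6 libraries. ENSSSCG00000026749 did not pass (log2 1.5 ± 0.51, adjusted p = 0.197). A second model with the protein name of CPT1A, ENSSSCG00000012881, rose from 6.90 ± 1.6 to 39.2 ± 1.5 CPM (adjusted p = 0.000587). Among members that did not pass, log2 values ran from that of ACADVL, an acyl-CoA dehydrogenase (0.90 ± 0.33 and 0.36 ± 0.26 CPM, log2 -1.28 ± 0.55, adjusted p = 0.285), to that of SLC25A20. The list median was 0.11 and its mean 0.78.

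PPARD itself, the receptor of GW0742, stood at 51.5 ± 3.8 CPM with DMSO and 55.7 ± 2.5 CPM with GW0742 (log2 0.11 ± 0.08, adjusted p = 0.499). None of the 10 tested PPAR and RXR receptors and cofactors passed in edgeR, over all genes or over the list alone. Camera gave the list an adjusted p of 0.76.

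**Figure D2:**
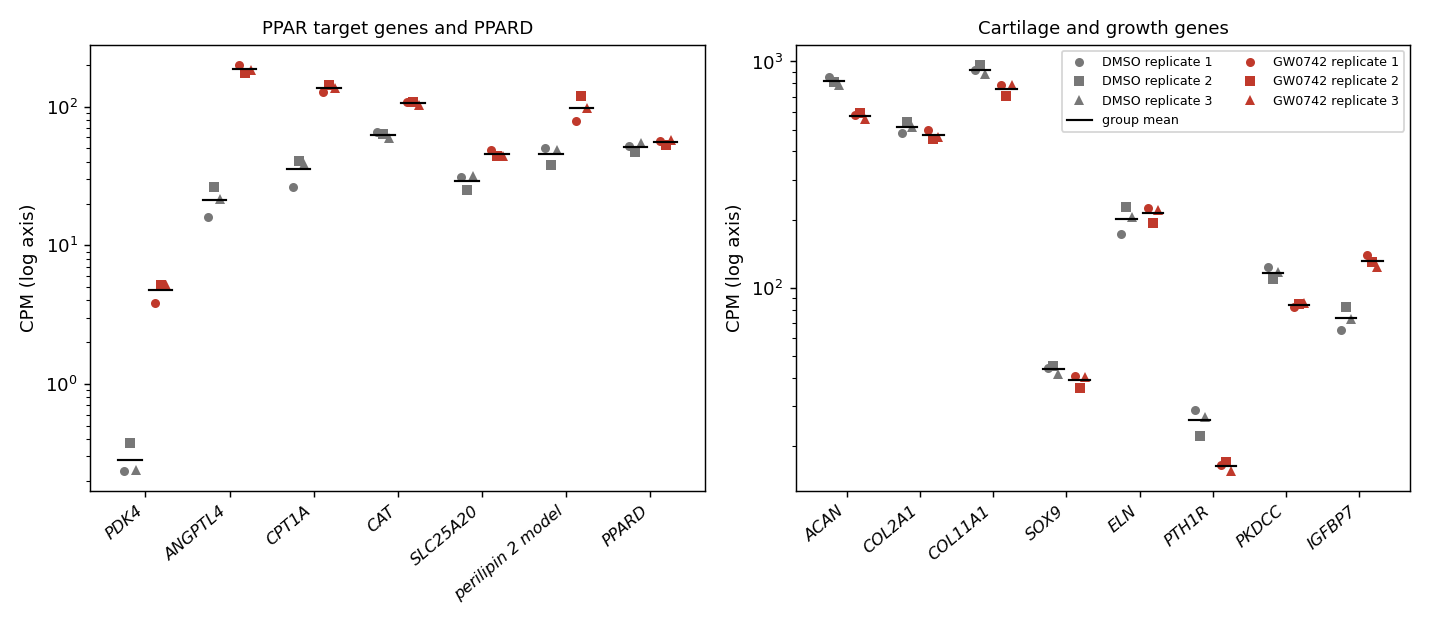
CPM of each library on a log axis for PPAR target genes with PPARD (left) and for cartilage and growth genes (right), DMSO in grey and GW0742 in red, with a bar at each group mean. ANGPTL4 goes from 21.3 to 187 CPM and ACAN from 816 to 577 CPM, while PPARD, COL2A1 and ELN overlap between groups.

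Of 19 tested cartilage matrix and chondrocyte markers, 1 fell in edgeR, ACAN (ENSSSCG00000001832), and 18 did not pass there. Adjusted over the list alone, 2 fell. ACAN changed by log2 -0.50 ± 0.06 (adjusted p = 0.0185), a call lost without DMSO replicate 1, DMSO replicate 3 or GW0742 replicate 1, with adjusted p-values up to 0.105 and log2 values between -0.53 and -0.47. COL11A1, a fibrillar collagen of cartilage, was 921 ± 44 and 758 ± 49 CPM (log2 -0.28 ± 0.07, edgeR adjusted p = 0.114). DESeq2 called it lower (adjusted p = 0.00683). SOX9, the master transcription factor of chondrocytes, was 43.7 ± 1.9 and 39.0 ± 2.6 CPM (adjusted p = 0.337), and COL2A1, the main collagen of cartilage, 511 ± 29 and 474 ± 23 CPM (adjusted p = 0.436). The list as a whole did not pass (camera, lower, adjusted p = 0.098). With DMSO, COL1A2 and VIM of the fibroblast and dedifferentiation list stood at 39570 and 13870 CPM. Among cartilage markers FMOD stood at 4362 CPM, HAPLN1 at 8.17 CPM and COL9A1 at 1.74 CPM. CPM is not scaled by model length, and the share of differentiated chondrocytes in these cultures was not measured. In edgeR none of 12 elastic fibre genes passed (adjusted p = 0.785 for the list by camera), and 1 was higher and 1 lower adjusted over the list alone. ELN, the elastin of the ear's elastic cartilage, was at 201 ± 27 and 213 ± 17 CPM (log2 0.08 ± 0.10, adjusted p = 0.738).

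PKDCC, a secreted kinase needed for long bone growth in mice, fell from 117 ± 7.2 to 84.1 ± 2.1 CPM (log2 -0.47 ± 0.07, adjusted p = 0.0369), and lost its call without DMSO replicate 1, DMSO replicate 3, GW0742 replicate 1 or GW0742 replicate 2 (adjusted p up to 0.18). PTH1R, the receptor of parathyroid hormone-related protein, was 25.9 ± 3.5 and 16.3 ± 0.71 CPM (log2 -0.67 ± 0.12, adjusted p = 0.0651), and passed in DESeq2 and without DMSO replicate 2 (adjusted p = 0.0431). In edgeR with all libraries none of 7 chondrocyte hypertrophy genes passed (list adjusted p = 0.375 by camera), though 3 were higher and 1 lower when adjusted over the list alone. Besides PTH1R, DESeq2 called the member MMP13 (adjusted p = 9.77e-07). IGFBP7, which binds insulin-like growth factors, rose from 73.4 ± 8.7 to 131 ± 8.4 CPM (log2 0.84 ± 0.09, adjusted p = 0.0152), and lost its call without DMSO replicate 1, DMSO replicate 3 or GW0742 replicate 1 (adjusted p up to 0.105). IGFBP7 was the 1 of 24 tested genes of IGF, TGF-beta, BMP and FGF signalling that passed in edgeR, and the list did not pass by camera (adjusted p = 0.375). Adjusted over the list alone, 1 member was higher and 2 were lower, and 17 of the 24 log2 values were below 0.

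The other genes with symbols that rose most were low in DMSO. DLL4, a Notch ligand of arterial endothelium, went from 0.96 ± 0.22 to 5.38 ± 1.89 CPM (log2 2.48 ± 0.33, adjusted p = 0.0333), and PDE1B, a cyclic nucleotide phosphodiesterase, from 2.92 ± 0.78 to 15.5 ± 2.2 CPM (log2 2.39 ± 0.21, adjusted p = 0.00384). In limma on log2(RPKM + 1) the log2 values were 0.95 for DLL4, which was not called there (adjusted p = 0.0974), and 1.62 for PDE1B, which was. The transcription factor KLF11 went from 7.12 ± 1.1 to 16.3 ± 2.4 CPM, and VCAM1, a leukocyte adhesion molecule, from 5.01 ± 0.39 to 10.3 ± 1.2 CPM. GEM, a small GTP-binding protein, and the cadherin CDH13 also rose (log2 1.01 ± 0.14 and 0.60 ± 0.08). Of these, PDE1B alone kept its call without each library. Those of DLL4, VCAM1, GEM and CDH13 held only without GW0742 replicate 3, and the adjusted p reached 0.195 otherwise.

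The genes with symbols that fell did so by modest amounts. ADRA1B, an adrenergic receptor, fell from 20.5 ± 1.5 to 12.8 ± 0.49 CPM (log2 -0.68 ± 0.10, adjusted p = 0.0437). RPL38, a ribosomal protein, fell from 243 ± 2.0 to 184 ± 5.6 CPM (log2 -0.40 ± 0.05), and NGEF, a guanine nucleotide exchange factor, from 138 ± 3.0 to 106 ± 2.8 CPM (log2 -0.37 ± 0.06). Leaving out any 1 library ended the calls of ADRA1B and NGEF (adjusted p up to 0.229), and RPL38 passed without 1 of the 6.

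Camera called 5 further lists higher and 1 lower, and none of these 6 held with an estimated correlation. None of their members passed singly over all genes in edgeR, though DESeq2 called some of them. Other fatty acid oxidation genes were higher (adjusted p = 0.0117; adjusted p = 0.407 with an estimated correlation). None of the 18 passed over all genes in edgeR, and 4 were higher adjusted over the list alone. ETFB, an electron carrier of beta-oxidation, stood at 56.1 ± 6.4 and 79.0 ± 2.1 CPM, and DESeq2 called it (adjusted p = 0.000345). ACADL, a long-chain acyl-CoA dehydrogenase, stood at 52.4 ± 1.4 and 64.0 ± 3.8 CPM, and DESeq2 did not call it. The call of this list was lost without GW0742 replicate 2 (adjusted p = 0.0574). Glycolysis and hypoxia genes were higher (adjusted p = 0.012, and 0.551 as the adjusted p with an estimated correlation), with 0 of 18 past the threshold in edgeR and 4 adjusted over the list alone, such as PFKL (log2 0.33 ± 0.08) and the oxygen sensor EGLN3 (log2 0.70 ± 0.13). Its call was lost without DMSO replicate 1 or GW0742 replicate 1 (adjusted p up to 0.108). Cell cycle genes were higher too (adjusted p = 0.012, and adjusted p = 0.592 with an estimated correlation). Of 20 log2 values 16 were above 0, with a median of 0.17, and none passed in edgeR over all genes or over the list alone. MCM2 (log2 0.37 ± 0.12, edgeR adjusted p = 0.195) overlapped between the groups. CCNE2 (log2 0.65 ± 0.23, edgeR adjusted p = 0.208) had the highest log2 value of the list, and DESeq2 called neither. Without DMSO replicate 2 or GW0742 replicate 2 that list was not called (adjusted p up to 0.459).

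Matrix proteases and inhibitors were higher as a list (adjusted p = 4.57e-05, and adjusted p = 0.407 with an estimated correlation). In edgeR 0 of 15 passed over all genes and 6 adjusted over the list alone. The collagenases MMP13 and MMP1 and the gelatinase MMP9 had the highest log2 values, at 3.29 ± 0.54, 2.00 ± 0.37 and 1.49 ± 0.26 (edgeR adjusted p = 0.0609, 0.073 and 0.0651). DESeq2 called MMP13, MMP1 and MMP9 (adjusted p = 9.77e-07, 4.2e-06 and 2.12e-06). The abundant members MMP2 and MMP14 had log2 values of -0.04 ± 0.08 and 0.10 ± 0.06. Markers of endothelial cells were higher as a list (adjusted p = 2.19e-05; adjusted p = 0.407 with an estimated correlation). All 6 tested markers had log2 values above 0, with a median of 1.36. TIE1 overlapped between the groups, at 0.46 CPM in GW0742 replicate 3 and 0.65 CPM in DMSO replicate 1. In edgeR 6 passed adjusted over the list alone but none over all genes. PECAM1, a junction protein of endothelium, was 11.7 ± 0.56 and 26.3 ± 9.8 CPM (edgeR adjusted p = 0.0977), and the VEGF receptor KDR was 1.42 ± 0.34 and 4.14 ± 1.9 CPM (edgeR adjusted p = 0.107). DESeq2 called PECAM1 (adjusted p = 0.000214) and KDR (adjusted p = 0.0156), but not TIE1, ESAM, EGFL7 or CLDN5.

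Some of these markers differed more between the GW0742 libraries than others. PECAM1 stood at 28.3, 35 and 15.6 CPM in GW0742 replicates 1, 2 and 3, MMP13 at 4.90, 8.35 and 1.96 CPM, and DLL4 at 5.44, 7.23 and 3.46 CPM. The markers CLDN5 and EGFL7 stood at 65.9, 66.3 and 62.4 CPM and at 18.1, 15 and 14.9 CPM, and ANGPTL4 at 200, 176 and 185 CPM, in the same libraries.

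**Figure D3:**
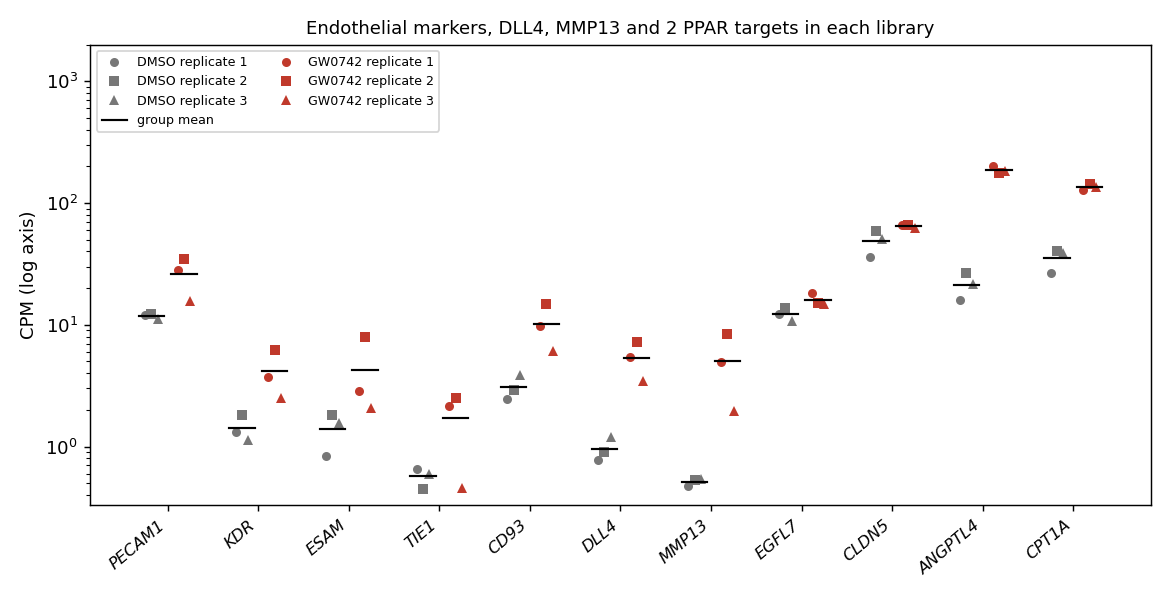
CPM of each library on a log axis for endothelial markers, DLL4, MMP13, ANGPTL4 and CPT1A, DMSO in grey and GW0742 in red, with a bar at each group mean. PECAM1 ranges from 15.6 to 35 CPM over the GW0742 libraries and ANGPTL4 from 176 to 200 CPM.

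Muscle and smooth muscle markers were lower as a list (adjusted p = 0.0152; adjusted p = 0.551 with an estimated correlation), and the call was lost without DMSO replicate 2 or GW0742 replicate 2 (adjusted p up to 0.081). In edgeR none of 7 passed over all genes and 3 were lower adjusted over the list alone. These 3 were contractile or cytoskeletal genes, with ACTA2 at 3704 ± 86 and 3031 ± 257 CPM, CNN1 at 629 ± 3.1 and 516 ± 29 CPM and DES at 428 ± 20 and 351 ± 46 CPM. DESeq2 called ACTA2 (adjusted p = 0.00562) and CNN1 (adjusted p = 0.00114), but not DES.

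The other tested lists did not pass by camera. These were fibroblast and dedifferentiation markers (adjusted p = 0.297, and 0.0496 without DMSO replicate 2), inflammatory mediators (0.299), with VCAM1 as 1 member that rose, interferon response (0.467), Wnt signalling (0.787) and p53 targets (0.585). Neither did cholesterol synthesis (0.831), fatty acid synthesis (0.467), ER stress (0.331), oxidative stress (0.467) and the respiratory chain (0.196). Adjusted over the list alone, 4 fibroblast and dedifferentiation markers were higher and 1 lower. Higher and lower counts were 3 and 2 for Wnt signalling, 2 and 1 for inflammatory mediators and 1 and 1 for p53 targets. They were 0 and 1 for fatty acid synthesis and for ER stress, and 1 and 0 for the respiratory chain. Interferon response, cholesterol synthesis and oxidative stress had none. Median, mean and test differed in sign for p53 targets (-0.13, 0.11, lower), Wnt signalling (-0.04, 0.01, higher) and inflammatory mediators (-0.01, 0.07, higher). Adipocyte, keratinocyte, immune cell, melanocyte and erythrocyte markers had 4, 3, 3, 2 and 0 tested members, too few for the list test. None of them passed in edgeR, over all genes or over the list alone.

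**Figure D4:**
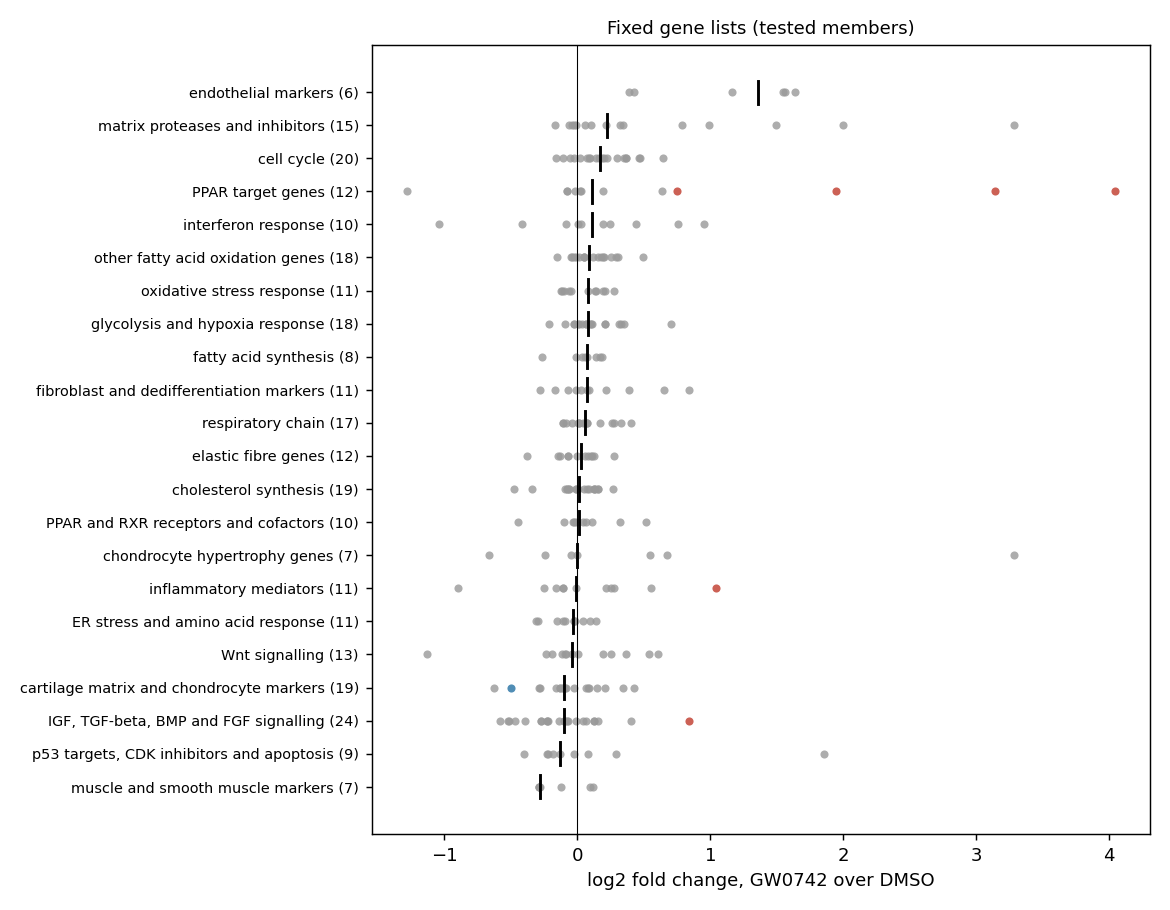
Log2 fold change (GW0742 over DMSO) of each tested member of the 22 tested gene lists, with a bar at the list median and the number of members in parentheses. Red and blue points passed an adjusted p of 0.05, and the endothelial markers have the highest median, 1.36.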

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

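Summed models, the robust prior and lists without called genes were chosen after seeing the data. Of 28 named genes and models past the threshold, 28 kept their direction in 13 alternatives and 6 kept their call in each of them: ANGPTL4, PDK4, CPT1A and its second model, CAT and PDE1B. Over named genes, 521 values stayed on their side, 173 lost the call and 19 gained it, 13 of these in DESeq2. ELN, which did not pass, ranged from -0.02 (without DMSO replicate 1) to 0.17 over left-out libraries. The number of genes higher was 26 and of genes lower 11. DESeq2 gave 207 and 234, with all 37 among them; the cause was not tested. Without a filter edgeR gave 13 and 3, over 19499 models. Limma gave 3 lower on log2(RPKM + 1), and 17 and 4 on log2(RPKM + 0.1). An adjusted p under 0.01 left 6 and 0 (1260 lower at an unadjusted p under 0.05), and a 2-fold minimum 4 lower. Summed models gave 44 and 20, and the robust prior 27 and 15. Leaving out 1 library gave 6 to 54 higher and 0 to 47 lower, with 6 to 27 of the 37 kept and fewer samples in each fit. Lists higher were 6 and lists lower 1; both an estimated correlation and fry left 1 and 0, while leaving out 1 library gave 4 to 6 and 0 to 1. Without called genes, 5 and 1 lists passed and the PPAR target list did not. The lists that passed hold no called gene, so nothing was taken from them and this alternative does not test them. The PPAR target list lost the members that these same data had called. With the replicate block, edgeR gave 10 higher and 0 lower, with 1102 lower at an unadjusted p under 0.05, and 6 and 1 lists. Deviations of same-numbered libraries correlated at 0.005, -0.032 and -0.103, so no shared effect of the number was visible. Whether same-numbered libraries were handled together cannot be told from these values. Size factors by median of ratios gave 26 and 11, the same 37 models. At this depth, spread and number of libraries edgeR recovered 44.8% of simulated 1.5-fold changes. Those were in genes at a mean of at least 1 CPM. The simulation gave 163 calls against 37 here, which makes the adjusted threshold easier to pass, so recovery in the data may be lower.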

Other observations

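The tests on gene splits and on shared protein names were chosen after the results were seen; those on list splits and on the second endothelial list were set before their values were seen.

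Some of the 20 called models without a symbol carry proteins of the extracellular matrix. All models given here were picked by hand after their values were seen, and such proteins were not tested as a group. A model of matrix Gla protein, an inhibitor of calcification made by chondrocytes (ENSSSCG00000000606), rose from 22.8 ± 2.7 to 47.2 ± 5.4 CPM (SD, n = 3; edgeR adjusted p = 0.015). Both models of collagen XVIII, a basement membrane collagen, rose (ENSSSCG00000030160, log2 0.51 ± 0.06; ENSSSCG00000028846, log2 0.41 ± 0.06), as did a model of nidogen-1, another basement membrane protein (ENSSSCG00000021913, log2 0.57 ± 0.09). Serum amyloid A2, an acute-phase protein (ENSSSCG00000028525), rose from 10.4 ± 1.3 to 43.7 ± 14.7 CPM, and a beta-nerve growth factor-like model (ENSSSCG00000021400) from 16.4 ± 1.9 to 30.4 ± 4.5 CPM. Myosin light chain 9 (ENSSSCG00000024230), a part of contractile myosin, fell from 1155 ± 19 to 899 ± 15 CPM (adjusted p = 0.0419). Leaving out 1 library ended most of these calls, with adjusted p-values up to 0.208.

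The cell cycle inhibitor CDKN1A is split over a pair of models and was singled out after its values were seen. The model with the symbol was not deep enough to test, at 0, 0.23 and 0.06 CPM in the DMSO libraries and 4.75, 0 and 16.4 CPM in the GW0742 libraries. The other, ENSSSCG00000022111, stood at 509 ± 18 and 422 ± 27 CPM (log2 -0.27 ± 0.07, adjusted p = 0.114). On-off models, at or under 3 reads in each library of a group and at least 1 CPM in each of the other, numbered 4, against at most 1 in other splits of the libraries. They carry no symbol, and 3 had at most 3 reads in each GW0742 library.

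The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 37 models by edgeR and the highest other 0, with 277 to 849 models at an unadjusted p under 0.05 and at most 24 in DESeq2. In both tests 1 split, the real one, reached its own count. For gene lists by camera the real split gave 7 and the highest other 6; with an estimated correlation the real split gave 1 and the others 0.

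Endothelial markers were higher with GW0742 as a list by camera, but not with an estimated correlation (adjusted p = 0.407) or by fry (adjusted p = 0.106), and 0 of 6 passed singly over all genes in edgeR, though all 6 did adjusted over the list alone. A candidate explanation is a larger share of endothelial cells in those libraries; the labels name no sort that would remove such cells. A second list of 30 endothelial genes, set before its values were seen, had 22 tested members. Its median log2 fold change was 0.82 ± 0.24 (SE over genes), against a bound of 0.58, with 19 of 22 above 0. That SE takes the genes as independent and does not measure the spread between libraries. It is too small where genes move together, and the first list had an estimated inter-gene correlation of 0.441. Both lists rest on the same libraries. None of the second list passed singly in edgeR. Its most abundant member, ERG, which cartilage also expresses, stood at 51.5 and 49.5 CPM, and CD34 went from 0.91 to 3.76 CPM. A response to GW0742 in endothelial cells already present would give the same values, was not tested, and stays open. Of the 6 markers 4 had a log2 ratio of GW0742 replicate 2 to replicate 3 of at least 1, while those of CLDN5 and EGFL7 were 0.09 and 0.01. Whether such a share also raised called genes was not decided and stays open.

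Of the 37 called models, 20 share a protein name with another tested model, and reads passed between gene models of one protein could account for such calls. The 20 were parted by the 95% interval of the summed CPM change of the other models. This form of the test was kept after these values were seen and other forms had been tried. In 8 the other models moved the same way beyond that interval, which argues against such a transfer for both models of CPT1A, of PDE1B and of collagen XVIII, for CDH13 and for the nidogen-1 model. The paired models of CPT1A, PDE1B and collagen XVIII each serve as the other's evidence, so the 8 are not independent. In 5 the interval fell short of a full transfer, which argues against it as the whole cause but not as part of it: the models of PLIN2, myosin light chain 9 and beta-nerve growth factor, ENSSSCG00000023570 and ENSSSCG00000026133. Of these, ENSSSCG00000026133 alone (-18.1 CPM) had another model, CMPK1, that moved the opposite way beyond its interval (6.7 CPM, 4.95 to 8.46). A partial transfer stays open there. In the other 7 the interval reached a full transfer, and in 2 of these (ENSSSCG00000027498 and ENSSSCG00000030306) the other models moved the opposite way beyond it. For these 7, which include the BCL6 model ENSSSCG00000024106 (3.38 to 14.9 CPM, beside 88.5 and 86.0 CPM for BCL6), a transfer and a change of the gene cannot be told apart, since the values of the other models allow both.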
